A study of Mus musculus with 5 samples.

How the data were processed

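Polyadenylated RNA of single cells was measured with 10x Genomics Chromium v4 dual index chemistry in 5 libraries, 1 per culture, each with a target of 5000 cells. The deposited count tables hold whole UMI counts per gene and cell, which the authors made with Cell Ranger 9.0.0 and Seurat against mm10, per the submitters' processing notes. The deposited percent values are mitochondrial percentages of each cell's UMIs, and the deposited counts of UMIs and genes per cell matched the tables. The authors had kept the cells deposited here by filters that the notes do not state: the fewest genes in a cell were 3014, 3001, 3002, 3002 and 5038 in the 2i/LIF, 24 h, 48 h, 96 h and AC libraries. The highest mitochondrial share was 9.80%, 6.80%, 8.71%, 9.98% and 9.93% in the same order. The tables held 19945 to 24458 genes, 18938 of them in all tables and 25253 in any, and a gene absent from a table was taken as 0 counts. Median genes per cell were 4682, 5684, 4454, 4353 and 8316. No table held tdTomato, so the reporter was not measured. Coordinates came from GENCODE vM21, on the assembly that mm10 names, which matched 24805 of 25253 symbols (98.2%).

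Counts were summed over the cells of a library, or of a class, and scaled by the sum of all counts to counts per 1000000 (CPM). Differences are log2((CPM + 1)/(CPM + 1)). Each sum has an exact Poisson 95% interval, and each share of cells a Clopper-Pearson 95% interval. For a share of 0 the upper limit is instead 3 cells of the total. With 1 library in each group no test between groups was made and no p-value is given. A gene list was described by the median log2 difference of its members present in the tables and by the number at least 2-fold apart. Only lists with 3 or more members at 5 CPM in 1 of the 2 sums are reported, and 1000 Poisson draws gave the interval of the median. The percentile of a list was taken among 10000 random lists of the same size, drawn within 20 bins of mean expression. There were 13 marker lists and 21 pathway lists with 395 gene symbols, 12 of them in no table. Of these, Ccn1, Ccn2 and H1-0 are other names of list members that are in the tables. Genes were named by a rule: 18 fixed genes of the lineages; the 8 largest increases and 8 largest decreases of each comparison among genes at 20 CPM or more, without predicted, clone-named, mitochondrial and ribosomal protein genes; and up to 4 members of each list at 20 CPM or more. A fold against a sum of 0 is a lower bound against a floor of 3 counts of that library or class. Where the gene was absent from a table, the bound assumes that no more counts had been filtered out. The calculation was tested on simulated data, Poisson draws of the 2i/LIF sum with 200 genes at 20 CPM or more changed 2-fold or 4-fold. The median log2 of genes at 20 CPM or more was subtracted first, a step not used in the comparisons. The median recovered log2 was then 0.989 and 1.99. This checks the arithmetic only, and not differences between libraries, cell composition or genes at low counts.

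Cells of the protocol libraries carried deposited types (EPI, PrE, TE, 2CL), which were used as classes. The AC library had cluster numbers without types, so its cells were clustered: 10000 counts per cell, log1p, genes in 10 or more cells, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, seed 1. A cluster took its name from the marker list with the highest median log2 against the other cells, among lists with a median of 1 or more and at least 3 markers and 50% of members at 5 CPM. It stayed unnamed if that list was not of Epi, PrE, TE or fibroblasts, or if any other list had more of the top 10 genes. The marker and pathway lists, the named-gene rule, the comparisons and most alternatives were fixed before the data were examined. The limits for naming clusters were set after the AC clusters had been seen, as was the choice of the lists and detection values that the report leads with, the classes of the same library that stand as background of detection, and the limit of 0.5 for a list median whose change of sign is reported. Classes of 20 cells or more were compared between the AC and 96 h libraries and within each library. For detection, each cell was thinned to 11000 UMIs, the 10th percentile over all cells rounded down, which left out 285, 70, 860, 710 and 0 cells of the 5 libraries.

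The alternatives were other pseudocounts (0.1 and 10 CPM), TMM factors (edgeR), DESeq2 size factors, sums without mitochondrial and ribosomal protein genes, means of per-cell CPM, list members at 20 CPM or more only, and cells without the lowest 20% and highest 5% by UMIs. Classes were also set by marker scores per cell, by Leiden resolutions of 0.25 and 1.0, by all libraries clustered together, and without cell cycle genes among the variable genes. Detection was repeated unthinned, at 0.5 of the depth and with at least 2 UMIs. Scrublet called 0.0399%, 0.0417%, 0.0748%, 1.39% and 0.104% of cells doublets, too few for libraries of this size, so that leaving them out tested little; leaving out the top 5% of scores was added. Other alternatives added after the data had been seen were sums without fibroblast-like cells, the authors' AC clusters, and own clusters of the protocol libraries with the deposited type of most of their cells. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.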

Results

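Single-cell RNA libraries were made at 5 stages of a culture of V6.5, a mouse embryonic stem cell line, carrying a tdTomato-CDX2 genotype. The starting culture was kept in 2i/LIF, the medium of kinase inhibitors and leukemia inhibitory factor that holds mouse embryonic stem cells in the naive state. The next cultures were taken after 24 h in a first medium (MLPM1), after 48 h, the last 24 of them in a second medium (MLPM2), and after 96 h, the last 48 of them as aggregates of 30 cells in a maturation medium (MLMM). The last culture had been kept for 12 passages on mouse embryonic fibroblasts in a medium that the labels call AC, without its composition. The labels give the aim of the 96 h regimen as epiblast (Epi), primitive endoderm (PrE) and trophectoderm (TE) cells, the lineages of the blastocyst. The 2i/LIF library held 5010 cells and 84376011 UMIs, the 24 h library 4797 cells and 112862525, the 48 h library 6684 cells and 104824044, and the 96 h library 5045 cells and 81563719. The AC library held 2871 cells and 251394044 UMIs, and its cells were the deepest, with a median of 84483 UMIs against 15064 to 23034 in the other libraries. Each culture had 1 library, so no difference has a replicate check. Intervals are 95%, exact for shares and CPM and from Poisson draws for list medians, and cover counting error only. The upper limit given with a share of 0 is 3 cells of the total. Each list percentile places its median among those of 10000 random lists matched on expression. Where members of a list are counted as higher or lower, the count is of members at least 2-fold apart. Further members can differ by less.

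The deposited cell types gave the composition of the 4 protocol libraries. Cells annotated EPI made up 95.4% (95% interval 94.8% to 95.95%) of the 2i/LIF library, 82.9% (95% interval 81.8% to 83.9%) at 24 h, 32.02% (95% interval 30.9% to 33.2%) at 48 h and 25.97% (95% interval 24.8% to 27.2%) at 96 h. PrE cells were not annotated in 2i/LIF (0 of 5010 cells, upper limit 0.0599%). They made up 5.04% of the cells at 24 h, 26.1% (95% interval 25.1% to 27.2%) at 48 h and 20.6% (95% interval 19.5% to 21.7%) at 96 h. TE cells were annotated from 48 h, as 17.4% (95% interval 16.5% to 18.3%) of the cells, and made up 53.4% (95% interval 52.1% to 54.8%) at 96 h. Cells annotated 2CL went from 4.61% in 2i/LIF to 12.1% at 24 h and 24.4% at 48 h, and were 0 of 5045 at 96 h (upper limit 0.0595%). Without the shallowest and deepest cells their share was 7.64% at 24 h. The AC library carried no deposited types. By its clusters and the marker lists, 514 cells were Epi-like (17.9%, 95% interval 16.5% to 19.4%), 434 PrE-like (15.1%, 95% interval 13.8% to 16.5%), 415 TE-like (14.5%, 95% interval 13.2% to 15.8%), 828 fibroblast-like (28.8%, 95% interval 27.2% to 30.5%) and 680 unnamed. Without the fibroblast-like cells, 25.2% of 2043 cells were Epi-like, 21.2% PrE-like and 20.3% TE-like. These shares moved with the cells and the clustering used. TE-like cells were 4.18% at a higher resolution, 25.8% at a lower one and 0 by the authors' own clusters, named by the same rule. Of those, a cluster of 611 cells had 21 of 27 TE genes at 5 CPM (median 1.61 against the other cells), but stayed unnamed with Fgf8, of the mesoderm list, among its top 10 genes. With all libraries clustered together, Epi-like cells were 31.9%, TE-like cells 22.5% and unnamed cells 0.453%. PrE-like cells were 8.17% without the shallowest and deepest cells. With classes set by marker scores per cell, PrE cells were 2.25% at 24 h, TE cells 31.2% at 48 h, EPI cells 16.00% at 96 h and PrE-like cells 56.3% in AC. The bar chart of class shares gives every class with its interval.

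**Figure D1:**
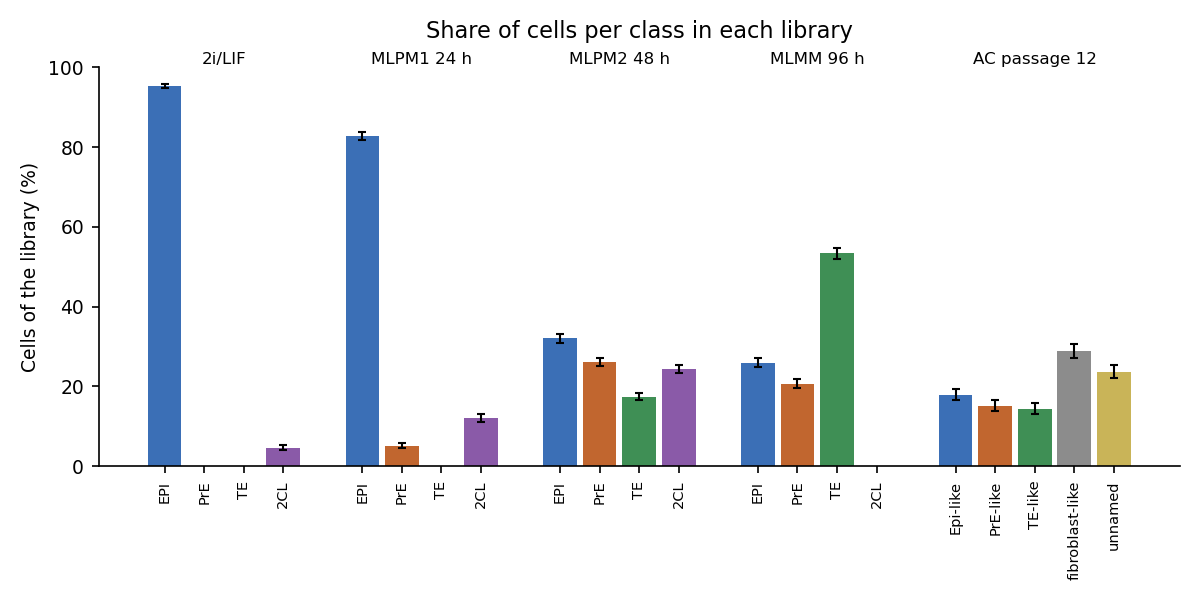
Bars give the percent of cells of each class in each of the 5 libraries, with Clopper-Pearson 95% intervals, for the deposited types in the 4 protocol libraries and for marker-named clusters in the AC library. EPI cells went from 95.4% in 2i/LIF to 25.97% at 96 h, where TE cells were 53.4%.

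Single markers were detected as follows with every cell thinned to 11000 UMIs, each beside a class of the same library that should lack the gene. Gata6, the earliest transcription factor of the PrE, lies on mm10 chromosome 18, 11052064 to 11085635, plus strand. It had a UMI in 41.4% of cells at 48 h, against 27.1% of TE cells of that library, and in 20.6% at 96 h, against 2.46% of TE cells. Gata4, which acts after Gata6, had a UMI in 15.9% (95% interval 14.99% to 16.9%) of cells at 48 h, against 1.94% of TE cells. Cdx2, the TE transcription factor, lies on mm10 chromosome 5, 147300805 to 147307270, minus strand. It was detected in 29.3% of cells at 24 h, 9.98% at 48 h and 18.5% at 96 h, against 10.04%, 2.13% and 3.55% of the PrE cells of the same libraries. Elf5, a gatekeeper of trophoblast fate, lies on mm10 chromosome 2, 103411688 to 103450989, plus strand. It was detected in 23.9% (95% interval 22.7% to 25.2%) of cells at 96 h, against 3.44% of PrE cells, and in at most 0.313% in any other library. Nanog, a core factor of the naive state, was detected in 44.1% of cells at 48 h and 11.6% at 96 h, against 11.96% and 3.95% of TE cells. In AC it was detected in 19.9% (95% interval 18.4% to 21.4%) of cells, against 0.362% of fibroblast-like cells. Zscan4d was detected in 10.1% (95% interval 9.38% to 10.95%) of cells at 48 h, against 3.07% (95% interval 2.08% to 4.35%) of TE cells. Median depths before thinning were 23034 UMIs at 24 h, 15064 at 48 h and 15353 at 96 h. They were 22503.5 in 24 h, 14879 in 48 h and 14921 in 96 h PrE cells, 14566 in 48 h and 15252 in 96 h TE cells, and 86891 in fibroblast-like cells. Unthinned, Gata6 was detected in 44.2% of cells and 31.4% of TE cells at 48 h, and Cdx2 in 48.5% of cells and 19.8% of PrE cells at 24 h. Nanog was detected in 29.5% of AC cells and 3.50% of fibroblast-like cells without thinning. Unthinned shares of Elf5 were 25.6% at 96 h and 3.85% in PrE cells. Those of Gata4 were 17.9% at 48 h and 2.32% in TE cells, and those of Zscan4d 13.1% and 4.21%.

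The 24 h and 2i/LIF libraries were compared for the first response to MLPM1, which holds the GSK3 inhibitor CHIR at 6 µM, the TGF-beta receptor inhibitor RepSox, the retinoic acid receptor agonist AM580 and the histone deacetylase inhibitor NaB. Retinoic acid targets were higher at 24 h: 11 of 14 were at least 2-fold higher, with a median log2 difference of 2.04 (95% interval 1.95 to 2.13). Stra8, which retinoic acid induces in germ cells before meiosis, lies on mm10 chromosome 6, 34920163 to 34939344, plus strand. It went from 2.71 CPM (95% interval 2.37 to 3.09) to 169 CPM (167 to 171). Hoxa5 went from 0.427 to 30.9 CPM, Hoxa1 from 1.75 to 39.7 CPM and Rbp1, a retinol carrier, from 5.78 to 58.7 CPM. With a pseudocount of 10 CPM in place of 1 the median was 0.56, and list medians here and below that rest on low counts shrink likewise. Germline genes were at least 2-fold higher in 10 of 12 members (median 2.19), with Tex101 from 1.21 to 91.3 CPM, Taf7l from 1.22 to 37.8 CPM and Sycp1, of the synaptonemal complex, from 10.9 to 106 CPM. Mageb4, another testis gene, went from 1.79 to 45.9 CPM. The genes of the 2-cell state were at least 2-fold higher in 19 of 19 members (median 1.90, 95% interval 1.84 to 2.07), with Zscan4d from 3.91 to 39.5 CPM. Zscan4d lies on mm10 chromosome 7, 11161374 to 11166159, minus strand, beside near-identical copies between which reads could be split. Of the WNT targets, 6 of 12 were at least 2-fold higher (median 1.04). Cdx1 went from 42.9 to 327 CPM, Axin2, the feedback inhibitor of the pathway, from 33.4 to 106 CPM, and T, the primitive streak factor, from 3.27 to 17.5 CPM. Hox genes were at least 2-fold higher in 16 of 27 members (median 1.66). The list percentiles were 100 for retinoic acid targets, 100 for germline, 100 for 2-cell, 100 for WNT and 100 for Hox genes. Some genes, such as Stra8, Hoxa1 and Hoxa5, were on more than 1 of these lists. TGF-beta and NODAL targets, chosen for RepSox, had a median of 0 with 3 of 9 at least 2-fold lower and 0 higher (percentile 16.29). Genes responsive to HDAC inhibitors, chosen for NaB, had one of 0.53, with 2 of 7 at least 2-fold higher and 1 lower (percentile 98.82).

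Of the PrE factors at 24 h, Gata6 went from 0.427 CPM (95% interval 0.299 to 0.591) to 43.04 CPM (41.8 to 44.3), Gata4 from 0.936 to 1.81 CPM, Sox17 from 0.415 to 3.86 CPM and Pdgfra from 0.367 to 1.54 CPM. The PrE list had a median of 0.58 (95% interval 0.46 to 0.66), with 6 of 23 members at least 2-fold higher and 3 of 23 lower. Over members at 20 CPM or more its median was -0.50, and with a pseudocount of 10 CPM it was 0.12. Cdx2 went from 1.69 to 36.5 CPM, with Elf5 at 0.399 CPM, Krt8 at 2.90 CPM and Fabp3 lower (124 to 22.6 CPM). The TE list had a median of 0.21. Targets of LIF signalling were lower, 5 of 8 of them at least 2-fold (median -1.83, 95% interval -1.88 to -1.79). Bcl3 went from 41.8 to 3.41 CPM and Socs3, the feedback inhibitor of the pathway, from 25.3 to 3.54 CPM. Spp1, which encodes osteopontin, went from 915 to 45.3 CPM, Ttn from 261 to 11.8 CPM and Upp1 from 169.8 to 18.9 CPM. The naive genes had a median of -0.35 (95% interval -0.38 to -0.34) with 4 of 18 at least 2-fold lower, among them Fgf4 (149 to 24.3 CPM) and Tdgf1 (284 to 68.4 CPM). Pou5f1 went from 972 to 825 CPM and Nanog from 285 to 237 CPM. The early response gene Egr1 went from 1.01 to 48.5 CPM; Dnmt3a, a de novo DNA methyltransferase, went from 9.94 to 46.3 CPM, and the epithelial adhesion gene Epcam from 62.5 to 291 CPM. Basement membrane genes were at least 2-fold lower in 4 of 10 members (median -0.61), with Nid1 from 99.4 to 29.9 CPM. The percentile was 0 for LIF targets, 0.25 for naive genes and 98.88 for PrE genes. Scaling by TMM factors moved the median of all genes to -0.25 and DESeq2 size factors to -0.29, from -0.03 by library totals, and the naive median to -0.58 and -0.61.

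The 48 h library was compared with the 24 h library for what differed after a day in MLPM2, which lacks NaB, holds CHIR at 3 µM and contains LIF again. PrE genes were higher: 14 of 23 members were at least 2-fold higher at 48 h, with a median log2 difference of 2.20 (95% interval 2.16 to 2.25). Pdgfra, a receptor that marks PrE cells, went from 1.54 CPM (95% interval 1.32 to 1.79) to 43.9 CPM (42.7 to 45.2), Gata4 from 1.81 to 35.4 CPM, Sox17 from 3.86 to 42.3 CPM and Gata6 from 43.04 to 202 CPM. Basement membrane genes, the secreted product of the PrE, were at least 2-fold higher in 5 of 10 members (median 1.27), with Lama1 from 12.1 to 131 CPM, Lamb1 from 17.9 to 156 CPM and Col4a1 from 5.23 to 50.4 CPM. Fgf10 went from 0.248 to 28.1 CPM and Dkk1, a secreted WNT inhibitor, from 1.30 to 37.02 CPM. LIF targets were higher again, 4 of 8 at least 2-fold (median 0.91, 95% interval 0.88 to 0.95). Socs3 went from 3.54 to 23.8 CPM, and Spp1 and Upp1, low at 24 h, went from 45.3 to 728 CPM and from 18.9 to 378 CPM. Retinoic acid targets moved apart (median 0.0196): Cyp26a1, which degrades retinoic acid, went from 2.80 to 54.8 CPM and Stra8 from 169 to 509 CPM. Meis2 went from 133 to 19.7 CPM. The 2-cell genes had a median of 0.46 (95% interval 0.36 to 0.52), with 4 of 19 at least 2-fold higher. Arg2 went from 20.9 to 58.9 CPM and Zscan4d from 39.5 to 49.3 CPM. The 2-cell median was 1.29 without the shallowest and deepest cells (14 of 19), 0.17 by the mean of per-cell CPM and 0.25 with a pseudocount of 10 CPM (1 of 19).

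Naive genes were lower at 48 h (median -0.61, 95% interval -0.65 to -0.56, 4 of 18 at least 2-fold), with Sox2 from 312 to 133 CPM, Nanog from 237 to 141 CPM and Tdh from 451 to 161 CPM. Such library sums do not stand for EPI cells alone, which went from 82.9% of cells at 24 h to 32.02% at 48 h. In 48 h EPI cells Nanog was at 238 CPM, and naive genes were not compared between the EPI cells of these libraries. Germline genes were at least 2-fold lower in 6 of 12 members (median -1.08). Tex101 went from 91.3 to 5.55 CPM and Dazl, an RNA-binding protein of germ cells, from 308 to 80.2 CPM; Fkbp6, another meiotic gene, went from 207 to 22.6 CPM. Cdx2 went from 36.5 to 12.4 CPM, T from 17.5 to 2.89 CPM and Cdx1 from 327 to 128 CPM. Id2 went from 4.20 to 36.3 CPM, Krt8 from 2.90 to 17.05 CPM and Fabp3 from 22.6 to 150.4 CPM. The TE list had a median of 0.39, with 8 of 27 at least 2-fold higher and Elf5 at 0.296 CPM. Nodal, a TGF-beta family ligand of the epiblast, went from 64.3 to 20.4 CPM. Among the largest decreases were the Y-linked genes Uty (23.5 to 1.46 CPM), Eif2s3y (23.6 to 1.61 CPM) and Ddx3y (28.8 to 2.44 CPM), while the sum of 4 X-linked copies went from 418 to 529 CPM. The Y-linked sum was 26.4 CPM in 2i/LIF, 76.4 at 24 h, 5.62 at 48 h, 93.3 at 96 h and 204 in AC. Of the 48 h cells with a Y-linked UMI, 39.2% (95% interval 34.1% to 44.4%) were 2CL and 24.2% EPI, against 23.6% (95% interval 22.6% to 24.7%) and 32.5% of those without. The percentile was 100 for PrE genes, 100 for basement membrane, 100 for LIF targets, 0 for naive and 0 for germline genes.

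**Figure D2:**
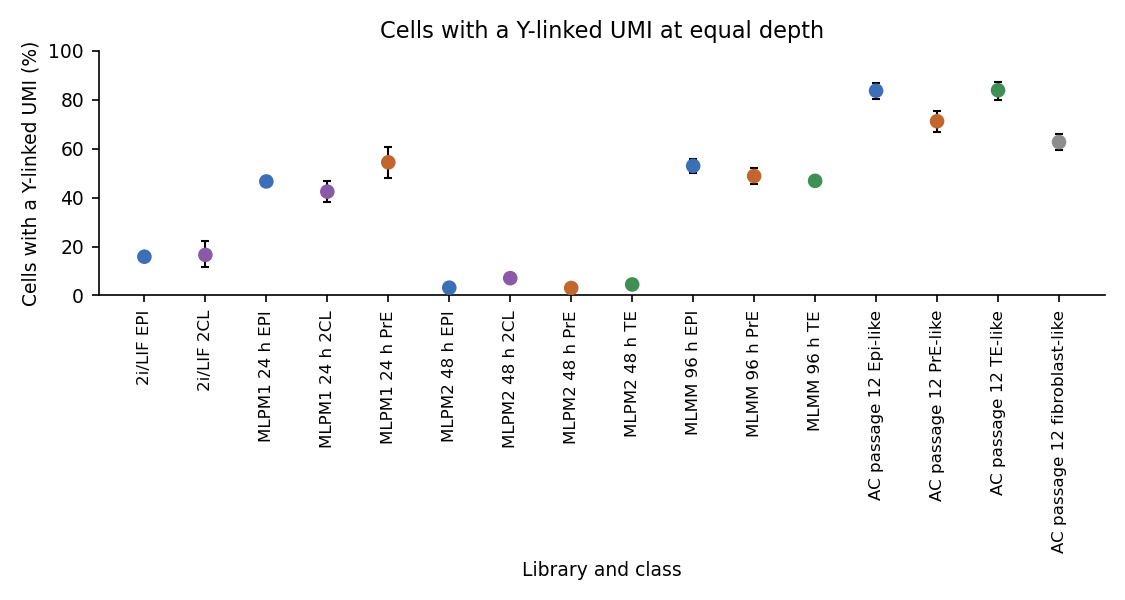
Points give the percent of cells of each class with a UMI of a Y-linked gene (Ddx3y, Uty, Eif2s3y, Kdm5d) after thinning to 11000 UMIs, with Clopper-Pearson 95% intervals, some of them smaller than the symbols. The 48 h classes lie between 3.06% and 7.07%, below those of the other libraries.

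The 96 h and 48 h libraries were compared for what differed after 48 h of aggregation in MLMM, which holds FGF4, activin A, the WNT pathway inhibitor XAV and the LATS kinase inhibitor TRULI. Genes of the visceral endoderm, the epithelium that the PrE forms around the epiblast, were at least 2-fold higher at 96 h in 9 of 9 members, with a median log2 difference of 4.09 (95% interval 4.02 to 4.17). Ttr, the transthyretin gene, lies on mm10 chromosome 18, 20665280 to 20674321, plus strand. It had no deposited UMI at 48 h and 198 CPM at 96 h, at least 6916-fold higher. With such genes set to 3 counts the list median was 4.05. Apoa1 went from 0.162 to 89.6 CPM, Apob from 0.506 to 94.1 CPM, Spink1 from 0.229 to 101 CPM and Cubn, the endocytic receptor cubilin, from 4.33 to 231 CPM. TE genes were at least 2-fold higher in 23 of 27 members (median 3.51, 95% interval 3.45 to 3.65). Elf5 went from 0.296 to 55.9 CPM, Hand1, a factor of trophoblast giant cells, from 0.773 to 78.3 CPM, Krt19 from 1.32 to 108 CPM, Plac1 from 1.66 to 99.98 CPM, Eomes from 9.90 to 122 CPM and Cdx2 from 12.4 to 27.6 CPM. Formative epiblast genes were at least 2-fold higher in 8 of 11 members (median 1.19), with Fgf5 from 0.343 to 46.9 CPM, Otx2 from 0.191 to 39.7 CPM and Pou3f1 from 6.63 to 192 CPM. These library sums do not stand for EPI cells alone. At 96 h, EPI cells had Fgf5 at 30.5, Otx2 at 65.6 and Pou3f1 at 256 CPM, and PrE cells had more Fgf5 and Otx2 than EPI cells. NODAL targets were higher too (median 1.71, 6 of 9), with the antagonist Lefty1 from 1.89 to 98.7 CPM (427 in PrE cells) and Lefty2 from 0.0668 to 57.1 CPM (60.2 in EPI cells). Keratin and tight junction genes were at least 2-fold higher in 9 of 12 members (median 2.96), with Cldn7 from 3.23 to 241 CPM and Krt18 from 15.1 to 460.5 CPM. Imprinted genes were at least 2-fold higher in 9 of 12 (median 1.62), with H19 from 0.544 to 99.1 CPM and Cdkn1c from 17.05 to 233 CPM. Glycolysis genes were at least 2-fold higher in 7 of 14 members (median 0.97), with the glucose transporter gene Slc2a1 from 86.8 to 574 CPM and Ldha from 208 to 992 CPM. The hypoxia gene Ndrg1 went from 2.48 to 51.8 CPM.

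The 2-cell genes were at least 2-fold lower in 19 of 19 members at 96 h (median -3.27, 95% interval -3.39 to -3.16), with Zscan4d from 49.3 to 0.748 CPM and Arg2 from 58.9 to 0.883 CPM. Stra8 went from 509 to 4.05 CPM, and retinoic acid targets were at least 2-fold lower in 9 of 14 members (median -1.77). WNT targets were at least 2-fold lower in 6 of 12 members (median -1.05). Cdx1 went from 128 to 2.01 CPM, Sp5 from 66.1 to 0.699 CPM and Axin2 from 92.5 to 4.32 CPM. Naive genes were at least 2-fold lower in 10 of 18 members (median -1.13, 95% interval -1.14 to -1.11), with Klf4 from 239.6 to 17.8 CPM, Nanog from 141 to 21.6 CPM and Tbx3 from 224 to 42.3 CPM. The DNA demethylase gene Tet2 went from 218 to 22.2 CPM. The PrE list had a median of 1.62, with 13 of 23 members at least 2-fold higher and 7 of 23 lower. Gata6 went from 202 to 57.2 CPM, Sox17 from 42.3 to 8.90 CPM and Pdgfra from 43.9 to 13.2 CPM, while Gata4 went from 35.4 to 53.7 CPM, Foxa2 from 8.32 to 17.3 CPM and Hnf1b from 4.81 to 17.9 CPM. YAP targets had a median of 1.05, with Cyr61 from 3.57 to 30.8 CPM. The percentile was 100 for visceral endoderm, 100 for TE, 100 for formative, 0 for 2-cell and 0 for naive genes. DESeq2 size factors moved the median of all genes from -0.03 to 0.13.

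Over the whole regimen, from 2i/LIF to 96 h, PrE, TE and formative genes were higher and naive genes lower. The PrE list was at least 2-fold higher in 20 of 23 members (median 4.11, 95% interval 4.00 to 4.21), with Cubn from 0.0830 to 231 CPM, the adaptor gene Dab2 from 0.770 to 369 CPM and Gata4 from 0.936 to 53.7 CPM. The visceral endoderm list was higher in 9 of 9, with a median of 4.09, or 4.04 with genes at 0 set to 3 counts. TE genes were higher in 26 of 27 members (median 4.20, 95% interval 4.05 to 4.23), with Krt18 from 1.65 to 460.5 CPM, Krt8 from 5.77 to 329 CPM and Elf5 from 0.0830 to 55.9 CPM. Car4, a carbonic anhydrase gene, had no deposited UMI in 2i/LIF and 178 CPM at 96 h, at least 5016-fold higher. Formative genes were at least 2-fold higher in 9 of 11 members (median 2.78, 95% interval 2.69 to 2.87), with Pou3f1 from 3.41 to 192 CPM and Fgf5 from 0.130 to 46.9 CPM. Fgf5 was higher in PrE than in EPI cells at 96 h. FGF-ERK targets were higher in 7 of 11 members (median 2.04), with Dusp4 from 0.936 to 23.04 CPM and Dusp6 from 6.08 to 39.8 CPM. Hypoxia genes were at least 2-fold higher in 6 of 10 (median 1.65), with Bnip3 from 4.40 to 97.3 CPM. Peg10, an imprinted gene needed in the placenta, went from 3.18 to 449 CPM, and Phlda2, which limits placental growth, from 10.5 to 378 CPM. Naive genes were at least 2-fold lower in 16 of 18 members (median -1.999, 95% interval -2.03 to -1.97). Prdm14 went from 20.2 to 0.356 CPM, Nanog from 285 to 21.6 CPM, Klf4 from 187 to 17.8 CPM, Esrrb from 160.5 to 42.7 CPM and Pou5f1 from 972 to 278 CPM. These sums do not stand for EPI cells alone, which were 95.4% of cells in 2i/LIF and 25.97% at 96 h. In 96 h EPI cells Nanog was at 72.02, Klf4 at 25.1, Esrrb at 52.8 and Pou5f1 at 882 CPM. The largest decreases included Trps1 (218 to 5.58 CPM), Jam2 (284 to 7.80 CPM), the receptor gene Kit (144 to 5.20 CPM) and Nr5a2 (189 to 7.22 CPM), a nuclear receptor that supports Pou5f1 expression. The DNA methylation enzymes moved both ways (median 0.52, or -0.60 over members at 20 CPM or more). Dnmt3b went from 84.8 to 393 CPM and Dnmt3l from 24.7 to 156 CPM. Tet2 went from 327 to 22.2 CPM. The percentile was 100 for PrE, 100 for TE, 100 for formative and 0 for naive genes. The plot of marker CPM by library shows these courses for 16 genes.

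**Figure D3:**
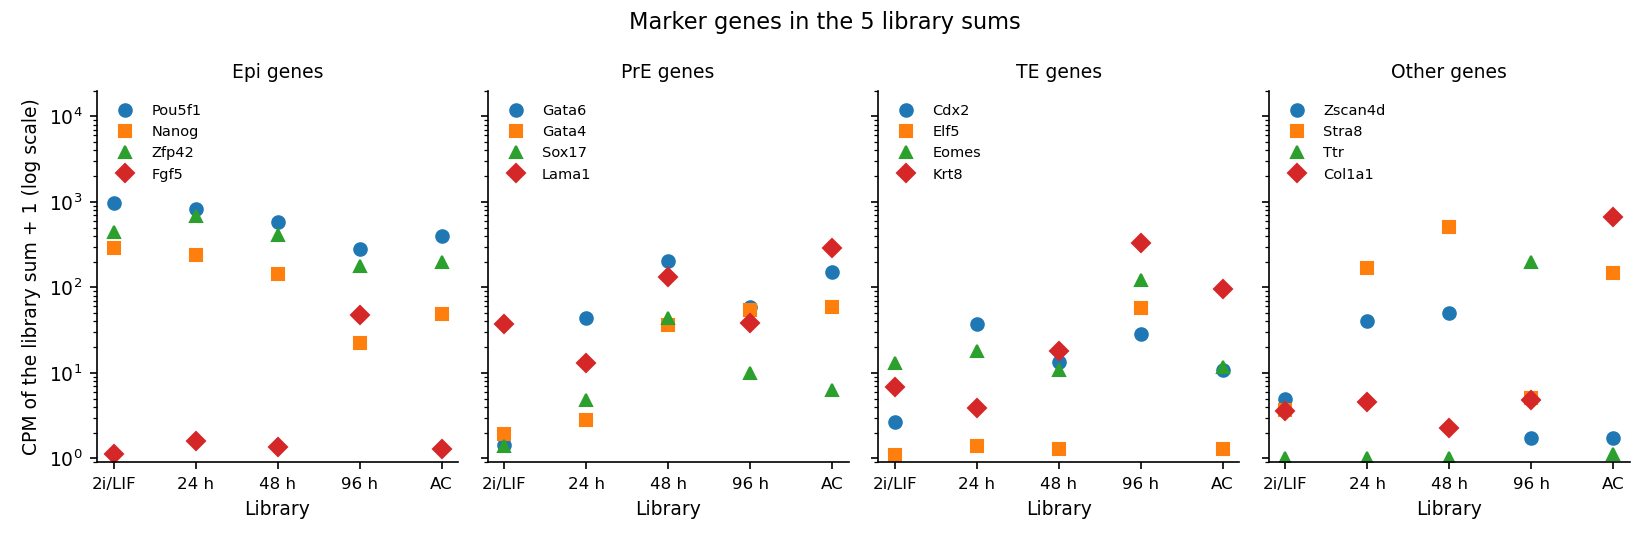
Points give the CPM of the library sum, plus 1, on a log axis for 16 marker genes in the 5 libraries, in 4 panels of Epi, PrE, TE and other genes. Fgf5 and Elf5 lie near the floor up to 48 h and reach 46.9 and 55.9 CPM at 96 h.

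The passaged AC culture was compared with the 96 h aggregates for how long-term culture differed from the end of the regimen. Fibroblast genes were at least 2-fold higher in AC in 15 of 15 members (median log2 5.45, 95% interval 5.37 to 5.56), with the collagen genes Col3a1 from 0.0490 to 659 CPM and Col1a1 from 3.85 to 658 CPM. Mgp had no deposited UMI at 96 h and 371 CPM in AC, at least 10076-fold higher. Without the fibroblast-like cells, 5 fibroblast genes were at least 2-fold higher, with a median of 0.57. WNT targets were at least 2-fold higher in 9 of 12 members (median 2.53), with Axin2 from 4.32 to 121 CPM, Cdx1 from 2.01 to 53.9 CPM and Nkd1 from 0.981 to 29.6 CPM. Retinoic acid targets were at least 2-fold higher in 10 of 14 (median 1.55), with the receptor gene Rarb from 1.78 to 94.2 CPM (227 in fibroblast-like cells) and Stra8 from 4.05 to 145 CPM. Parietal endoderm genes, of the PrE derivative that lays down Reichert's membrane, had a median of 3.47 over 5 members, or 0.26 without the fibroblast-like cells, in which Plat (4.70 to 62.1 CPM) was at 198 CPM. In PrE-like against 96 h PrE cells it was 1.76, with 3 of 5 at least 2-fold higher. Basement membrane genes had one of 1.54, with Lama1 from 37.5 to 289 CPM and Nid1 from 27.8 to 188 CPM (552 in fibroblast-like cells). Klf4 went from 17.8 to 155 CPM, Pdgfra from 13.2 to 118 CPM (209 in fibroblast-like cells) and Gata6 from 57.2 to 148 CPM. The p53 target Cdkn1a went from 118 to 501 CPM, and was at 1193 CPM in fibroblast-like, 87.4 in Epi-like, 144 in PrE-like and 286 in TE-like cells. The p53 targets had a median of 0.68, and of 0.0403 without the fibroblast-like cells. Against the like class at 96 h it was -0.34 in Epi-like, -0.66 in PrE-like and 0.26 in TE-like cells. The visceral endoderm list was at least 2-fold lower in 9 of 9 members (median -3.53, 95% interval -3.64 to -3.46), with Ttr from 198 to 0.139 CPM and Apob from 94.1 to 0.402 CPM. TE genes were at least 2-fold lower in 21 of 27 members (median -2.34, 95% interval -2.40 to -2.30), with Elf5 from 55.9 to 0.282 CPM, Hand1 from 78.3 to 0.505 CPM and Eomes from 122 to 10.6 CPM. Formative genes were at least 2-fold lower in 8 of 11 (median -2.05), with Pou3f1 from 192 to 1.07 CPM and Fgf5, higher in PrE than in EPI cells at 96 h, from 46.9 to 0.274 CPM. NODAL targets (median -1.46), keratins and junctions (median -2.21), glycolysis genes (median -1.05) and cholesterol synthesis genes (median -0.94, or -0.55 without the fibroblast-like cells) were lower too. Among them were Lefty2 from 57.1 to 0.0438 CPM, Cldn7 from 241 to 13.2 CPM, Slc2a1 from 574 to 108 CPM and Insig1 from 70.02 to 20.8 CPM. Immediate early genes had a median of 0.91, with Fos from 5.55 to 105 CPM, and stress response genes one of 0.56. Without the fibroblast-like cells these medians were -0.0911 and -0.0803. Hspb1, a further large decrease (1035 to 18.1 CPM), was low in every AC class. The percentile was 100 for fibroblast, 100 for WNT, 0 for visceral endoderm, 0 for TE and 0 for formative genes.

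Against 2i/LIF, the AC culture had higher PrE and retinoic acid genes and lower naive genes. PrE genes were at least 2-fold higher in 20 of 23 members (median 3.26, 95% interval 3.19 to 3.35), with Gata6 from 0.427 to 148 CPM, Pdgfra from 0.367 to 118 CPM and Col4a1 from 3.18 to 507 CPM. In fibroblast-like cells Pdgfra was at 209 and Col4a1 at 610 CPM, and in PrE-like cells at 291 and 2688. Basement membrane genes were at least 2-fold higher in 6 of 10 (median 2.20, 95% interval 2.17 to 2.23). TE genes were at least 2-fold higher in 17 of 27 members (median 1.57), with Krt18 from 1.65 to 112 CPM and Esx1, an X-linked placental factor, from 1.02 to 40.7 CPM, while Elf5 was at 0.282 CPM and Eomes at 10.6. Retinoic acid targets were at least 2-fold higher in 11 of 14 members (median 4.51, or 2.46 without the fibroblast-like cells), with Dhrs3 from 0.652 to 65.6 CPM (195 in fibroblast-like cells) and Rarb from 1.56 to 94.2 CPM. Fibroblast genes were higher in 15 of 15 (median 6.13, 95% interval 6.07 to 6.15, 6.08 with genes at 0 set to 3 counts), with Col1a1 from 2.56 to 658 CPM. Without the fibroblast-like cells, 7 fibroblast genes were at least 2-fold higher. Imprinted genes were at least 2-fold higher in 9 of 12 members (median 2.09), with Peg10 from 3.18 to 245 CPM. The p53 targets had a median of 0.85, or 0.17 without the fibroblast-like cells, in which Mdm2 (90.5 to 291 CPM) was at 673 CPM. Naive genes were at least 2-fold lower in 15 of 18 members (median -1.91, 95% interval -1.94 to -1.89, or -1.42 without the fibroblast-like cells). Fgf4 went from 149 to 1.28 CPM, Klf2 from 443 to 8.998 CPM, Tdgf1 from 284 to 29.3 CPM and Nanog from 285 to 47.7 CPM. Klf4 went from 187 to 155 CPM and Esrrb from 160.5 to 70.6 CPM. In Epi-like cells alone Nanog was at 193, Klf4 at 239 and Esrrb at 144 CPM, while Fgf4 was at 5.26 and Klf2 at 34.5 CPM. Other large decreases, of Hspb1 (1223 to 18.1 CPM), Chchd10 (423 to 5.93 CPM), Hist1h2ae (120.0 to 3.46 CPM) and Taf10 (191 to 7.39 CPM), belonged to 23 genes that were below 0.25 of their lowest protocol class in every class of the AC library, fibroblast-like cells included. For the 2i/LIF, 24 h, 48 h and 96 h libraries the same count was 0, 0, 0 and 1. Rbmxl2 (318 to 2.18 CPM) and Sap30 (189 to 6.95 CPM) were low in every AC class as well. The percentile was 100 for PrE, 100 for retinoic acid, 100 for TE and 0 for naive genes. Scaling by TMM and DESeq2 factors put the median of all genes at -0.20 and -0.26 here, in place of 0.00538, and at -0.10 and -0.18 against 96 h, in place of 0.0773.

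Within the protocol libraries, the summed counts of the annotated classes describe the classes and do not test them, because the types had been assigned from expression. At 24 h, the 242 PrE cells had Gata6 at 405 CPM against 26.1 in EPI cells, Sox17 at 30.1 against 2.08 and Runx1 at 58.9 against 2.13, with 12 of 23 PrE genes at least 2-fold higher (median 1.24). At 48 h the PrE cells carried 19 of 23 (median 3.61), with Pdgfra at 162 against 2.27 CPM, Gata4 at 128 against 3.23 and Dkk1 at 132 against 2.50, and had Nanog at 17.5 against 238. The 48 h TE cells had Id2 at 147 against 4.04 CPM, Esx1 at 118 against 3.03, Ascl2 at 62.9 against 3.90. They had Hoxb8 at 40.8 against 5.69, Lef1 at 49.5 against 5.58 and Msx1 at 30.2 against 0.841. The Hox list had a median of 0.44, with 11 of 27 at least 2-fold higher and 1 of 27 lower. The TE list had a median of 1.54, with 17 of 27 at least 2-fold higher. Of the 24 TE genes at 20 CPM or more in 96 h TE cells, 15 were below 0.1 of that level in 48 h TE cells. Among them were Elf5 (0.970 against 99.8 CPM), Krt8 (15.9 against 574 CPM) and Hand1 (2.68 against 138 CPM). Cdx2 was at 88.6% of its 96 h level. In 2CL cells 19 of 19 genes of the 2-cell list were at least 2-fold higher than in EPI cells in each library (medians 4.27, 5.88 and 4.69 in 2i/LIF, at 24 h and at 48 h). Zscan4d was at 83.8 against 0.260 CPM in EPI cells in 2i/LIF, 372 against 0.993 at 24 h and 199.9 against 3.53 at 48 h, where Dppa3, a maternal-effect gene, was at 259 against 41.95. At 96 h, PrE cells had higher visceral endoderm genes (9 of 9, median 5.57), with Ttr at 968 against 8.28 CPM, Cubn at 1131 against 8.66 and Lhx1 at 259.7 against 2.60. The PrE list had a median of 4.78 (22 of 23). The 96 h TE cells had 24 of 27 TE genes at least 2-fold higher than EPI cells (median 3.45), with Elf5 at 99.8 against 1.80 CPM and Eomes at 149 against 17.4. Against PrE cells they had Phlda2 at 646 against 20.3 CPM and Cdkn1c at 403 against 11.6, with imprinted genes at a median of 1.81. The AC classes had been named by these same marker lists, so their marker values describe them and test nothing. In AC, PrE-like cells had Col4a1 at 2688 against 4.30 CPM in Epi-like cells and Gata4 at 388 against 1.43 (PrE list 5.69, 22 of 23). TE-like cells had Krt18 at 600.0 against 6.12, Esx1 at 231 against 3.32 and H19 at 84.9 against 1.86 (TE list 2.46, 21 of 27). Fibroblast-like cells had Col1a1 at 2190.1 against 6.002, with G2/M phase genes lower in 14 of 14 members (median -4.34). The heat map of class markers shows 28 genes in 16 classes.

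**Figure D4:**
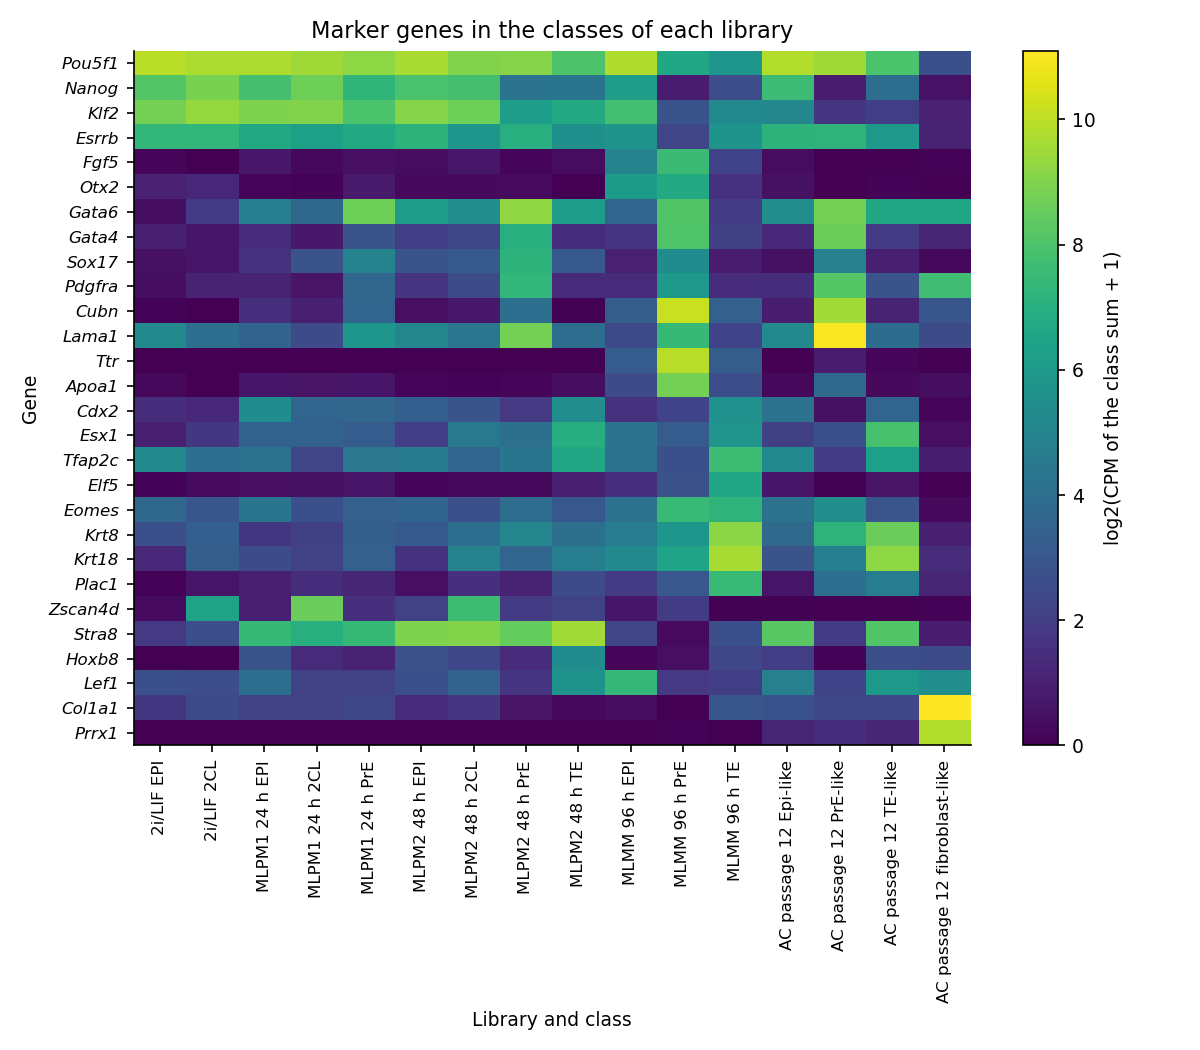
Colour gives log2(CPM + 1) of 28 marker genes (vertical axis) in the summed counts of 16 classes (horizontal axis), the deposited types of the protocol libraries and the marker-named classes of the AC library. Ttr stands at 968 CPM in 96 h PrE cells and at 0.870 CPM in AC PrE-like cells.

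Like classes were then compared between AC and 96 h, for how the passaged cells of a lineage differed from those of the aggregates. Epi-like cells had lower formative genes than 96 h EPI cells: 9 of 11 were at least 2-fold lower (median log2 -2.86, 95% interval -3.06 to -2.76), with Pou3f1 from 256 to 0.626 CPM, Otx2 from 65.6 to 0.430 CPM, Fgf5 from 30.5 to 0.293 CPM and Dnmt3a from 177 to 10.3 CPM. Naive genes were at least 2-fold higher in 7 of 18 members and at least 2-fold lower in 5 of 18 (median 0.46, 95% interval 0.39 to 0.52). Klf4 went from 25.1 to 239 CPM, Nanog from 72.02 to 193 CPM, Esrrb from 52.8 to 144 CPM and Tfcp2l1 from 68.6 to 305 CPM. Fgf4 went from 138 to 5.26 CPM and Klf2 from 219 to 34.5 CPM. Pou5f1 went from 882 to 906 CPM. LIF targets were at least 2-fold higher in 5 of 8 members (median 1.37), retinoic acid targets in 9 of 14 (median 1.13, 1.08 with genes at 0 set to 3 counts) and Hox genes in 16 of 27 (median 1.48, 1.29 likewise). Stra8 went from 3.93 to 309 CPM, Cdx1 from 0.710 to 118 CPM and Hoxa7 from 0.662 to 57.1 CPM. The Epi-like class joined clusters of 395 and 119 cells, and Stra8 was among the top 10 genes of the smaller one only. NODAL targets were lower (median -1.07), with Lefty2 from 60.2 to 0.117 CPM, as were glycolysis genes (median -0.997), with Eno1 from 429 to 99.3 CPM and Ldha from 1089 to 304 CPM, and Tcf15, a factor of the formative transition, went from 160.3 to 1.66 CPM. Col1a1, Col1a2, Col3a1 and Sparc together stood at 1.55% of their fibroblast-like level in these cells. Scand1, another of the largest decreases (40.1 to 0.235 CPM), was low in every AC class. The percentile was 0 for formative, 99.97 for naive, 100 for Hox and 0 for glycolysis genes.

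PrE-like cells had lower visceral endoderm genes than 96 h PrE cells: 9 of 9 were at least 2-fold lower (median -5.34, 95% interval -5.51 to -5.12), with Ttr from 968 to 0.870 CPM and Afp from 47.3 to 0.113 CPM. Amn, the partner of cubilin, went from 889 to 3.21 CPM, Hnf4a from 60.9 to 3.86 CPM, Lhx1 from 259.7 to 0.945 CPM and Fgf8 from 156 to 0.303 CPM. Otx2 and Fgf5 had no UMI in PrE-like cells, at least 966-fold and 1648-fold lower than at 96 h. NODAL targets were at least 2-fold lower in 7 of 9 members (median -2.79, -2.63 with genes at 0 set to 3 counts), with Lefty1 from 427 to 1.36 CPM and Nodal from 41.2 to 0.265 CPM. Cholesterol synthesis genes were at least 2-fold lower in 12 of 13 (median -1.96), with Msmo1 from 453 to 37.9 CPM and Insig1 from 135 to 12.9 CPM. Basement membrane genes were higher in 8 of 10 members (median 2.10), with Lama1 from 174 to 2087 CPM, Lamb1 from 191 to 1889 CPM and Hspg2, which encodes perlecan, from 87.3 to 656 CPM. The PrE list itself had a median of 0.54 (95% interval 0.49 to 0.58), or 0.28 at the higher clustering resolution, with Gata6 from 267 to 436 CPM, Gata4 from 259.8 to 388 CPM and Pdgfra from 60.04 to 291 CPM, and Igf1 went from 1.68 to 364 CPM. Esrrb went from 4.04 to 148 CPM, Pou5f1 from 98.3 to 731 CPM and Nanog from 0.807 to 0.794 CPM. The percentile was 0 for visceral endoderm, 0 for cholesterol and 100 for basement membrane genes.

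TE-like cells had 17 of 27 TE genes at least 2-fold lower than 96 h TE cells (median -1.64, 95% interval -1.67 to -1.55), with Elf5 from 99.8 to 0.488 CPM, Hand1 from 138 to 2.44 CPM, Wnt6 from 110.0 to 2.82 CPM, Eomes from 149 to 6.57 CPM and Cdx2 from 48.5 to 11.4 CPM. Gata3 went from 23.1 to 30.5 CPM. WNT targets were at least 2-fold higher in 12 of 12 members (median 3.28), with Axin2 from 2.71 to 208 CPM, Lef1 from 3.20 to 58.7 CPM and Notum from 1.49 to 28.5 CPM. Stra8 went from 5.48 to 269 CPM and Gata6 from 2.89 to 98.1 CPM. Cebpb went from 193 to 1.71 CPM and Perp from 191 to 19.97 CPM. The percentile was 0 for TE genes and 100 for WNT targets. S phase genes had a median of 0.62, with Pcna from 69.1 to 156 CPM. At the higher clustering resolution the TE-like class held 4.18% of the AC cells. The TE list then had a median of -0.84, the naive list -0.71 in place of 0.59, and keratins and junctions 0.0445 in place of -0.98.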

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

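The tests of depth, of cells without a Y chromosome, of the AC library as a whole and both tests of the 48 h TE class were chosen after the result was seen. The deposited cell tables hold the authors' own TRUE or FALSE marks for TE, PrE and pluripotent cells, from gene lists not given here, which no comparison used. In 2i/LIF, 0 of 5010 cells carried the TE or PrE mark, which allows a share of up to 0.0599%. The marks below exceeded that limit. At 24 h, 16 of 4797 cells were marked TE, although none was typed TE. At 48 h, 53 cells were marked TE against 1164 typed TE, with 46 in both, and 627 were marked PrE against 1747 typed, with 608 in both. At 96 h, 2163 cells were marked TE against 2696 typed, with 2032 in both, and 1055 PrE against 1039 typed, with 1018 in both. Below the limit, 1 of 4797 cells at 24 h was marked PrE, against 242 typed PrE. Pluripotent marks were on 613 cells at 96 h, against 1310 typed EPI, with 523 in both.

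The share of cells with a Y-linked UMI had no order in time: 15.9% in 2i/LIF, 46.5% at 24 h, 4.26% at 48 h, 48.9% at 96 h and 74.7% in AC, all at 1 thinned depth. The tables argue against depth, since the 24 h share was still 10.9 times the 48 h share, and against a joint change of X and Y copies, since the X-linked copies at 48 h stood at 1.27 times their 24 h level. They also argue against lower transcription alike in every 48 h cell as the only cause. UMIs of Ddx3y or Uty and of Eif2s3y or Kdm5d fell on the same cells 5.72 times as often as independence gives, in 0.419% of 6684 cells. In 2i/LIF this ratio was 3.09. The lower limit at 48 h was 3.80, and within classes it ran from 1.58 (2CL) to 4.39 (TE). The bound set beforehand was 2, which 2CL and PrE cells (1.73) did not pass, so within those classes the cause stays open. These values are from unthinned cells, whose depths differ, and they cannot exclude lower transcription beside a mixture of cells. Cells without a Y chromosome remain open: 6.27% of AC cells outside the fibroblast-like class had no Y-linked UMI, and the median Xist count of those 128 cells was 0. Of them, 64 were PrE-like, 14.7% of the shallowest AC class (median 57274 UMIs). In Epi-like and TE-like cells the share was 2.72% and 3.37%. The cultures may have held different parts of cells without a Y, which the 48 h shares and differences may carry. Beyond the above no biological explanation was tested, because the design names none.

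Genes of AC Epi-like cells stood apart from those of the protocol libraries. Across expressed genes, median log2 differed by -0.0804 between the 20% with the highest and with the lowest GC content, and by 0.0416 for transcript length. These values argue against a broad bias by either, but medians over so many genes cannot exclude a bias in a subset of them. Feeder RNA as a broad cause was argued against by collagen and Sparc counts at 1.55% of the fibroblast-like level. That value cannot exclude it for genes with low counts. The fibroblast list had a median of 0.46 in Epi-like against 96 h EPI cells. Of its 15 members, 5 were at least 2-fold higher, 1 was lower and 3 were at 5 CPM. A difference of the whole AC library in capturing or counting some genes stays open and fits for 23 genes, Taf10, Hspb1, Chchd10, Alyref, Hras and Mrps24 among them, that were low in every AC class. Their median GC content was 55.1%, against 48.3% of the 3441 genes at 30 CPM or more in every protocol class. None of the 23 was on a gene list, but 1 of the 8 largest decreases against 96 h and 4 of 8 against 2i/LIF were among them. The medium and the passages, which differ between AC and 96 h, stay open for the other genes and were not separated by the design.

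The class typed TE at 48 h carried few TE genes at the level of 96 h. Too few counts do not explain this: the upper limit of Elf5, Gata3, Hand1 and Krt8 together was 0.0294 of the 96 h level. A minority of cells like those at 96 h among others stays open: the level relative to 96 h differed 42.9-fold between the 90th and 10th percentile of TE genes, with Esx1 at 215%, Cdx2 at 88.6%, Ascl2 at 82.4% and Elf5 at 0.971%. This would exclude such a minority only if the other cells carried no TE genes, and Cdx2 stood at 84.6% of its 96 h TE level in 24 h EPI cells already. An early or other state with Cdx2 and Esx1 may also account for the class, which no further value tested.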

How the results depend on the processing

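The alternatives named in the methods as added later were chosen after the result was seen. Of 6407 alternative values of 774 results, 4406 stayed within the counting interval, or within 1.5 times for a count, 1992 moved and 9 changed sign. A change of sign was counted for list medians of at least 0.5 and named genes at least 2-fold apart. All 9 were list medians, out of 1289 alternative values of 151 medians of that size, and none of 165 such genes changed sign. Of 105 smaller medians, 26 changed sign under an alternative (48 of 863 values), as did 6 of 35 smaller gene differences. Counting intervals are narrow at this depth, so small shifts count as moved. For the main results 312 of 468 values stayed the same; the others are given below, and the cause was not tested except where the setting itself removes counts, cells or members. No paired analysis was possible because each group has 1 library. Doublets called by Scrublet were too few for that alternative to tell anything, and the other resolutions, the joint clustering, the clustering without cell cycle genes and the authors' clusters were applied only to AC, which carried no deposited types.

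Without the lowest 20% and highest 5% of cells by UMIs, the shares were 2i/LIF EPI 96.3%, 2i/LIF 2CL 3.70%, 24 h EPI 87.4%, 24 h 2CL 7.64%, 48 h EPI 35.2% and 48 h 2CL 21.8%. The others were 96 h EPI 28.9%, 96 h TE 51.1%, AC Epi-like 20.5%, AC PrE-like 8.17%, AC fibroblast-like 31.2% and AC unnamed 25.6%. With classes from marker scores per cell, the shares were 2i/LIF EPI 99.7%, 24 h EPI 94.8%, 24 h PrE 2.25%, 48 h EPI 43.1% and 48 h TE 31.2%. The others were 96 h EPI 16.00%, 96 h PrE 22.4%, 96 h TE 61.6%, AC PrE-like 56.3% and AC TE-like 25.4%. With own clusters given the deposited type of most cells, the shares were 48 h EPI 28.7%, 48 h PrE 28.8% and 48 h TE 18.4%. With all libraries clustered together, the shares were AC Epi-like 31.9%, AC TE-like 22.5% and AC unnamed 0.453%. Without cell cycle, mitochondrial and ribosomal genes among the variable genes, the shares were AC Epi-like 20.3%, AC TE-like 4.18% and AC unnamed 32.1%. At Leiden resolution 1.0, the shares were AC PrE-like 18.9%, AC TE-like 4.18% and AC unnamed 30.2%. At Leiden resolution 0.25, the shares were AC TE-like 25.8% and AC unnamed 11.1%. By the authors' deposited clusters, the shares were AC TE-like 0% and AC unnamed 36.7%. The cause was not tested.

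Without the lowest 20% and highest 5% of cells by UMIs, medians from 24 h to 48 h were 2-cell 1.29 (14 at least 2-fold higher). From 48 h to 96 h, the median was 2-cell -2.84. Over the whole regimen, medians were formative 2.88 and TE 3.95. In AC against 96 h, the median was visceral endoderm -3.70. In AC against 2i/LIF, medians were fibroblast 6.16 and basement membrane 2.05. At Leiden resolution 1.0, medians in PrE-like against PrE cells were PrE 0.28 and germline 0.38 in place of -0.89. In TE-like against TE cells, medians were naive -0.71 in place of 0.59, TE -0.84 and keratin and junction 0.0445 in place of -0.98. With a pseudocount of 10 CPM, medians from 2i/LIF to 24 h were naive -0.33, PrE 0.12 (2 at least 2-fold higher) and retinoic acid 0.56 (6 at least 2-fold higher). At 48 h against 24 h, medians were PrE 0.85 and 2-cell 0.25 (1 at least 2-fold higher). After aggregation, medians were visceral endoderm 1.91, TE 1.98 and 2-cell -1.01 (10 at least 2-fold lower). Comparing 96 h with 2i/LIF, medians were formative 1.78, PrE 1.97 and TE 2.07. From 96 h to AC, medians were visceral endoderm -1.93 and fibroblast 2.94. Comparing AC with 2i/LIF, medians were fibroblast 3.00 and basement membrane 2.07. In Epi-like against EPI cells, medians were naive 0.39 and formative -1.92. In PrE-like against PrE cells, the median was visceral endoderm -3.82. In TE-like against TE cells, the median was TE -1.44. By TMM factors, medians from 2i/LIF to 24 h were naive -0.58 and PrE 0.41. From 24 h to 48 h, medians were PrE 2.28 and 2-cell 0.53. From 48 h to 96 h, the median was visceral endoderm 4.19. In AC against 96 h, medians were visceral endoderm -3.65 and fibroblast 5.35. In AC against 2i/LIF, medians were fibroblast 6.05 and basement membrane 1.996. By DESeq2 size factors, medians from 2i/LIF to 24 h were naive -0.61 and PrE 0.39. At 48 h against 24 h, medians were PrE 2.29 and 2-cell 0.54. After aggregation, medians were visceral endoderm 4.26 and TE 3.67. Over the whole regimen, the median was PrE 4.27. From 96 h to AC, medians were visceral endoderm -3.72 and fibroblast 5.33. Comparing AC with 2i/LIF, medians were fibroblast 6.05 and basement membrane 1.93. With mitochondrial and ribosomal protein genes left out, medians from 2i/LIF to 24 h were naive -0.32 and retinoic acid 2.29. From 48 h to 96 h, medians were visceral endoderm 4.39 and 2-cell -3.55. Comparing 96 h with 2i/LIF, the median was PrE 4.39. In AC against 96 h, medians were visceral endoderm -3.70 and fibroblast 5.68. In AC against 2i/LIF, medians were fibroblast 6.48 and basement membrane 2.24. With a pseudocount of 0.1 CPM, medians from 2i/LIF to 24 h were PrE 0.89 (10 at least 2-fold higher) and retinoic acid 3.31. From 24 h to 48 h, the median was PrE 2.34. After aggregation, medians were visceral endoderm 7.28, TE 3.95 and 2-cell -5.86. Over the whole regimen, medians were formative 2.88, PrE 5.35 and TE 4.64. From 96 h to AC, medians were visceral endoderm -4.80 and fibroblast 7.33. Comparing AC with 2i/LIF, the median was fibroblast 8.70. Over members with at least 20 CPM, medians from 2i/LIF to 24 h were PrE -0.50 in place of 0.58 (2 at least 2-fold higher) and retinoic acid 3.51 (5 at least 2-fold higher). At 48 h against 24 h, medians were PrE 3.05 (8 at least 2-fold higher), 2-cell 0.56 and keratin and junction -0.13 in place of 0.52. From 48 h to 96 h, medians were visceral endoderm 6.28 (5 at least 2-fold higher), TE 3.73 and 2-cell -4.85 (7 at least 2-fold lower). Comparing 96 h with 2i/LIF, medians were formative 3.06, PrE 5.12 (13 at least 2-fold higher), TE 4.28, DNA methylation enzyme -0.60 in place of 0.52 and HDAC-inhibitor responsive -0.64 in place of 0.54. In AC against 96 h, the median was visceral endoderm -5.53 (5 at least 2-fold lower). By the mean of per-cell CPM, medians from 24 h to 48 h were 2-cell 0.17. After aggregation, medians were visceral endoderm 4.20 and 2-cell -3.50. From 96 h to AC, the median was visceral endoderm -3.68. In AC against 2i/LIF, medians were fibroblast 5.95 and basement membrane 2.39. Without the fibroblast-like cells of the AC library, medians in AC against 96 h were visceral endoderm -3.34, fibroblast 0.57 (5 at least 2-fold higher), stress response -0.0803 in place of 0.56 and immediate early -0.0911 in place of 0.91. Comparing AC with 2i/LIF, medians were fibroblast 0.97 (7 at least 2-fold higher) and basement membrane 1.90. Without the 5% of cells with the highest Scrublet scores, medians in PrE-like against PrE cells were PrE 0.49. The cause was not tested.

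Thinned to 0.5 of the depth, detection was Nanog 13.8% (AC), Gata4 11.3% (48 h), Zscan4d 8.30% (48 h) and Elf5 16.02% (96 h). Unthinned, detection was Nanog 29.5% (AC), Gata4 17.9% (48 h), Zscan4d 13.1% (48 h) and Elf5 25.6% (96 h). At a minimum of 2 UMIs, detection was Nanog 12.1% (AC), Gata4 9.43% (48 h), Zscan4d 5.34% (48 h) and Elf5 14.7% (96 h). These shares follow the counts kept, so depth limits them.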

Other observations

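The comparisons with the unnamed AC clusters and the Xist counts were chosen after the result was seen, and the autosome test before. An AC cluster of 359 cells met the limits of no marker list; nearest was primitive streak and mesoderm, with 5 of 13 members at 5 CPM and a median of 2.21 against the other cells. Dcc, a netrin receptor gene, was at 533 CPM against 0.723 in Epi-like cells, Fgf8 at 32.4 against 0.332, Nkd1 at 132 against 1.70, Lef1 at 375 against 27.3 and Hoxb3 at 62.6 against 3.68. WNT targets had a median of 1.97 (8 of 12 at least 2-fold higher), Hox genes 1.07 (15 of 27) and naive genes -4.43 (17 of 18 lower), with Pou5f1 at 19.04 against 906 CPM. A second cluster, of 295 cells, had PrE genes 19 of 23 at least 2-fold higher than Epi-like cells (median 3.52) and naive genes at a median of -1.14. In it Pdgfra was at 208 against 1.76 CPM, Gata4 at 134 against 1.43, Gata6 at 455 against 43.4 and Lamb1 at 362 against 10.2, while Zscan4d was at 7.10 CPM. Against all other AC cells, this cluster was not set apart by PrE genes (median 0.20), and naive genes had a median of 0.50. The 2-cell genes, 4 of 19 of them at 5 CPM, had one of 3.04. Of the smallest unnamed clusters, that of 21 cells had a median doublet score of 0.253, and that of 5 cells was led by Cdh19 and Sox10, genes of glial cells.

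Fibroblast-like cells had S phase genes at a median of -3.28 against Epi-like cells (13 of 13 at least 2-fold lower) and p53 targets at 1.37 (6 of 11 higher). Hypoxia genes stood at 2.39 (6 of 10), with Adm at 117 against 0.508 CPM. The cystine transporter gene Slc7a11, of the stress response list, was at 151 against 1.04 CPM. No Y-linked UMI was found in 257 of 828 fibroblast-like cells, and their median Xist count was 63, against 0 in those with a Y-linked UMI.

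Gain or loss of a whole autosome in most AC cells was tested as a further hypothesis for the AC differences, and no autosome passed the bound. Among 19 autosomes, the largest shift shared by Epi-like, PrE-like and TE-like cells against 2i/LIF EPI cells was 0.0311 in median log2, on chromosome 14, against a bound of 0.3.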
